A study of Rattus norvegicus with 15 samples.

How the data were processed

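Gene expression was measured in 15 samples of sorted rat hepatocytes, 5 each with a DNA content of 2c, 4c and 8c, on 1 one-colour Cy3 array per sample. Per the file headers, the arrays were read with Agilent Feature Extraction 11.5.1.1, while the submitters' notes name version 10.7.3.1. The deposited array files give the intensity of each spot on a linear scale, and the processed signal used here is the authors' background-subtracted and spatially detrended intensity, with no normalization between arrays. Each array held 62976 spots, 4259 of them controls, and all arrays were scanned on 1 date in 2 runs that match the 2 slides. No spot was saturated.

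Control spots and spots marked as outliers (264 to 539 per array) were left out, and the spots of a probe were averaged, which gave 45598 probes, 34 of them with no value on at least 1 array. On average 44.0% of the probes were well above background, the flag that the extraction software sets. Signals were taken to log2 and the 75th percentile over the 16211 probes well above background on all arrays was subtracted from each array, so a level of 0 is that percentile. Probes were named through their accession (21109), by a symbol of the reference table (6684), through a synonym (424), or kept the name in the file (17381). A probe was tested if it was well above background on at least 5 of the 15 arrays, and a gene with several such probes (2871 genes) was represented by the brightest. Probe positions refer to the rn4 assembly given in the files. No annotation of that assembly was at hand, so the part of the gene under a probe is not stated.

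Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the DNA content as the group and the experiment as a block, since the fractions of an experiment came from 1 isolation. All 15 arrays entered 1 fit. For 8c against 2c, 4c against 2c and 8c against 4c, p values were two-sided and adjusted after Benjamini and Hochberg over the 17279 tested features, and a gene passed at an adjusted p under 0.05. Residual and prior degrees of freedom together had a median of 10.2. The dependence of the 8c against 2c difference on age was an interaction term in the same model. The place of 4c was described by the ratio of fitted differences and was not tested. The floor of an array is its lowest level among probes well above background. Where a gene was above background on fewer than 5 arrays of the lower group, its fold is given as a lower bound with the dim arrays at their floor, and list medians were also computed with such genes at that bound.

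Before the data were examined, 30 gene lists were fixed from textbook knowledge of the liver and of the cell cycle: S phase, G2 phase and mitosis, ploidy regulators, p53 targets, periportal and pericentral genes, fetal liver genes, markers of cholangiocytes, sinusoidal endothelial cells, Kupffer cells, stellate cells, lymphocytes, neutrophils, erythroid cells and platelets, MHC class II, hepatocyte identity, acute phase, cytochrome P450, cholesterol synthesis, fatty acid synthesis and oxidation, bile acids, respiratory chain, ribosome biogenesis, immediate early genes, glycolysis, unfolded protein response, Nrf2 targets, YAP targets and the interferon response. The 27 lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, adjusted over 81 tests. Of these 35 passed, 0 of them with the correlation estimated from the data (lowest adjusted p = 0.0777), and 26 of the 81 passed with fry. Camera with the preset correlation compares a list with the other genes, while fry asks whether its members move 1 way on balance.

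The genes to be named were set by a rule fixed before the data were examined. It took, per comparison, the 10 largest rises and 10 largest falls among genes that passed, moved the same way in all 5 experiments, had a symbol and were well above background on every array of at least 1 group. It added up to 4 passing members of each list, or the 1 or 2 brightest where none passed, and always Alb, Afp, Mki67, Top2a, Ccnb1, Cdk1, Ccnd1, Glul, Cyp2e1, Ass1, Sox9, Epcam, Stab2, Clec4f and Dcn. Dcn was not measured.

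The procedure was tested on simulated data with the means and spread of the real arrays and genes that vary independently of each other. With 200 changed genes and the mitosis list raised as a block, 8c against 2c recovered 35.8% of those changed by log2 0.5, 74.6% at 1 and 97.0% at 2, with 7.01% of 157 calls on unchanged genes. With no gene changed it made 0 calls in each comparison. Of 78 tests of the other lists, 2 passed. Not all of these lists were without change, since the ploidy regulators share members with the raised mitosis list. The 2 are thus no rate of false calls.

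Alternatives covered the scaling (quantile normalization, the median, the 75th percentile over all probes), normexp background correction with an offset of 50, the filter on dim probes, the deposited value table, the mean of a gene's probes, array quality weights, eBayes with trend and robust, a requirement of 2-fold, the replicate block, the slide, fits of only the 2 groups compared, and leaving out each experiment and each array. The use of array quality weights stopped before its convergence tolerance was reached. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.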

Results

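Hepatocytes of female Wistar rats were stained with a dye that binds DNA and sorted by their DNA content into 2c, 4c and 8c cells, where 2c is the content of a diploid cell before replication. Hepatocytes become polyploid as the liver matures, and the series asks how the transcriptomes of cells of different ploidy compare. RNA of each sorted fraction was hybridised to a one-colour rat expression array. Each of 5 experiments gave 1 array per fraction, 15 arrays in all and n = 5 per group. The animals were 12, 14, 6, 5 and 6 weeks old in experiments 1 to 5, and the number of animals behind each experiment is not stated. How the gates were set is not stated, nor whether they left out doublets, cells after replication or cells other than hepatocytes. By DNA content alone a 4c event can be a tetraploid cell or a diploid cell after replication, and an 8c event likewise an octoploid cell or a tetraploid cell after replication. Each array was scaled to its own 75th percentile, so all values are relative levels within the RNA of a fraction, not amounts per cell.

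On each array 39.5% to 47.4% of 45598 probes lay well above background, and 17279 features, 10927 of them with a gene symbol, were tested. The number of arrays limits the precision. The first principal component held 38.2% of the variance and set the experiments apart rather than the fractions. Arrays of 1 experiment also resembled each other. After each group's mean was removed, the 15 pairs from the same experiment correlated across genes with a median of 0.58 (0.04 to 0.79). For pairs from different experiments the median was -0.13, which the removal of the group means pushes below 0 once the former are positive. Slide 1 held all arrays of experiments 1 and 2 and the 2c and 4c arrays of experiment 3, and slide 2 held the rest. On 6 arrays transcripts of pancreatic acinar cells were abundant: the median over 26 acinar genes was 1.09 on 2c and -1.77 on 8c of experiment 1, 4.41, 0.98 and 3.26 on 2c, 4c and 8c of experiment 2, and -1.48 on 8c of experiment 3, against -7.09 or lower on the remaining arrays (log2, where 0 is the array's 75th percentile). None of the 26 genes passed the test in any of the 3 comparisons.

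**Figure D1:**
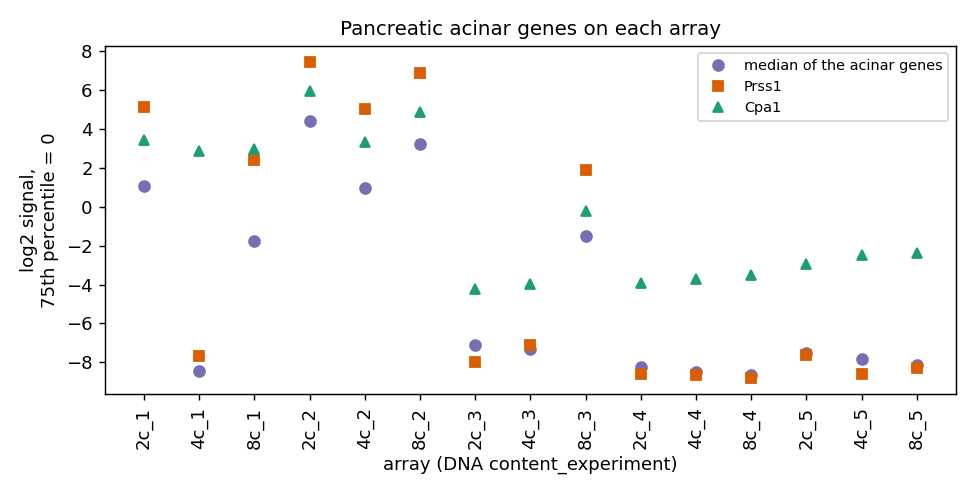
Signal of pancreatic acinar genes on each of the 15 arrays (log2, 75th percentile of the array = 0), as the median over 26 genes and for Prss1 and Cpa1. The median lies above -5 on 6 arrays, those of experiments 1 and 2 except 4c of experiment 1, and 8c of experiment 3.

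The comparison of 8c with 2c cells asks how hepatocytes at the ends of the sorted range differ. Genes of G2 phase and mitosis were higher in 8c, genes of hepatocytes around the central vein were lower, and markers of Kupffer, stellate and endothelial cells were far lower. Of 33 measured genes of G2 phase and mitosis, 29 were higher in 8c, with a median log2 difference of 2.37 over the list. Of 21 pericentral genes, 13 were lower, with a median of -0.76, and of 42 markers of the 3 other liver cell types, 26 were lower. Of 24 genes that define hepatocytes, among them the albumin gene Alb, 0 passed the test. In all, 140 genes were higher and 266 lower in 8c, 66 and 134 of them by at least 2-fold (limma, adjusted p under 0.05). The balance depends on the scaling, with 186 higher and 214 lower with the median as the scaling point, 177 and 201 with quantile normalization, and 226 and 191 with the 75th percentile over all probes.

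Among the mitotic genes, Cdk1, the kinase that drives entry into mitosis, was at least 8.01-fold higher in 8c (log2 difference 3.00, SE 0.34, adjusted p = 0.00254). Its probe lies on chromosome 20, 20043755 to 20043814, in the rn4 assembly that the files give. Its partner cyclin Ccnb1 was at least 7.88-fold higher (SE 0.40 on the log2 scale, adjusted p = 0.00362), the mitotic kinase Plk1 at least 8.86-fold (SE 0.30, adjusted p = 0.00103) and the cytokinesis factor Ect2 at least 7.28-fold (SE 0.40, adjusted p = 0.0041). These folds are lower bounds because the genes were well above background on 4, 3, 4 and 2 of the 5 2c arrays, and on all 5 8c arrays. Mki67, a marker of proliferating cells measured on all arrays of both groups, was 5.18-fold higher (log2 difference 2.37, SE 0.24, adjusted p = 0.00132). All 5 were higher in 5 of 5 experiments. Knstrn, Troap, Cenpw and Spag5, genes of the spindle and kinetochore that stood in no list, were at least 10.9-fold, 6.42-fold, 7.61-fold and 6.11-fold higher. The list's median ranged from 0.99 in experiment 2 to 2.89 between experiments (SD 0.80), and was 2.19 with dim arrays set to their floor, 0.68 with normexp background correction and 1.095 among features well above background on all arrays. Adjusted over the list alone 32 of the 33 genes were higher. The list passed the camera set test (adjusted p = 5.46e-50), but not with a correlation estimated from the data (adjusted p = 0.0777).

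Of 28 genes of S phase, 2 were higher in 8c and 1 was lower, 4 and 6 adjusted over the list alone, and the list did not pass (median -0.08, mean 0.02, adjusted p = 0.899). The pair that was higher were Rrm2, a subunit of ribonucleotide reductase (6.84-fold, SE 0.36, adjusted p = 0.00436), and Tk1, a thymidine kinase (1.76-fold, SE 0.16, adjusted p = 0.0288). Mcm2, a subunit of the replicative helicase, was lower (log2 difference -0.71, SE 0.12, adjusted p = 0.0157). The cyclin gene Ccnd1 did not pass (log2 difference -0.15, SE 0.13, adjusted p = 0.636). Of 22 regulators of hepatocyte ploidy 6 were higher, most of them mitotic genes, among them Foxm1 (2.15-fold, SE 0.19, adjusted p = 0.0157). That list's median was only 0.05, its call (adjusted p = 0.0135) was lost with an estimated correlation (adjusted p = 0.201), and the sign of its median turned with normexp background correction (-0.08), without a filter on dim probes (-0.009) and with the mean of a gene's probes (-0.009). Of 16 p53 targets 1 was higher, the cell cycle inhibitor Cdkn1a (1.69-fold, SE 0.14, adjusted p = 0.0242), and 3 adjusted over the list alone, and the list did not pass (median -0.02, mean 0.02).

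Pericentral genes were lower in 8c than in 2c. Glul, the glutamine synthetase of the hepatocytes next to the central vein, was 9.47-fold lower in 8c than in 2c (log2 difference -3.24, SE 0.28, adjusted p = 0.00103). The glutamate transporter gene Slc1a2 was 9.69-fold lower (SE 0.28, adjusted p = 0.00103), Rhbg, which carries ammonium, 3.18-fold (SE 0.23, adjusted p = 0.00538), Slc13a3 3.61-fold (SE 0.29, adjusted p = 0.00853), and Cyp7a1, the first enzyme of the classic bile acid pathway, 3.08-fold (SE 0.28, adjusted p = 0.015). Cyp1a2 and Cyp2e1, which metabolise drugs, were 1.71-fold and 1.42-fold lower (adjusted p = 0.0135 and adjusted p = 0.0304). Every one of these 7 genes was lower in 5 of 5 experiments. Of the 21 pericentral genes 18 were lower adjusted over the list alone, and the list passed (adjusted p = 9.27e-22; adjusted p = 0.0777 with an estimated correlation). Of 21 periportal genes 4 were higher in 8c, Hsd17b13, Hal, Uroc1 and the urea cycle gene Arg1, by 1.26-fold to 1.47-fold, and 9 were higher adjusted over the list alone. Ass1, a urea cycle gene with periportal expression, had a log2 difference of 0.22 (SE 0.11, adjusted p = 0.379). The periportal median was 0.21 (adjusted p = 5.68e-09; adjusted p = 0.161 with an estimated correlation), 0.13 without experiment 2 and 0.33 without experiment 4.

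Many markers of Kupffer, stellate and sinusoidal endothelial cells were higher in the 2c than in the 8c arrays. Clec4f, a Kupffer cell receptor, was at least 32.4-fold lower in 8c (log2 difference -5.16, SE 0.80, adjusted p = 0.0089), with a mean level of 0.45 in 2c (SD 1.84) and -4.71 in 8c (SD 2.09). Its probe lies on chromosome 4, 117839920 to 117839979. The complement gene C1qb was at least 17-fold lower (SE 0.63), Colec11 of stellate cells at least 30.1-fold (SE 0.76), the matrix gene Bgn 29.2-fold (SE 0.73) and the endothelial receptor Kdr at least 14.9-fold (SE 0.67), with adjusted p from 0.00801 to 0.0116. The medians of the lists were -3.25 for 16 Kupffer cell markers (12 lower), -3.60 for 13 stellate cell markers (8 lower) and -2.32 for 13 sinusoidal endothelial markers (6 lower), or -2.90, -2.91 and -1.70 with dim arrays at their floor. With normexp background correction they were -1.05, -1.04 and -0.57, and without the filter on dim probes the stellate and endothelial medians were -0.37 and -1.31. Among features well above background on all arrays the Kupffer median was -1.01, and the stellate and endothelial calls were lost (-0.33, adjusted p = 0.0723, and -0.22, adjusted p = 0.266). Adjusted over the list alone, 14, 9 and 9 were lower, and 1 stellate marker was higher. All 3 lists passed (adjusted p = 1.73e-13, adjusted p = 3.44e-10 and adjusted p = 8.02e-09), and none with an estimated correlation (adjusted p = 0.156, adjusted p = 0.126 and adjusted p = 0.126). The differences varied widely: the Kupffer median ranged from -5.91 to -0.95 between experiments, and the endothelial median was -1.52 without experiment 1 and -0.84 without experiment 3. Cd14 and Vwf, also members of these lists, had mean levels of 0.08 and 1.86 in 8c against -0.06 and 1.88 in 2c (log2). Ramp1, a partner protein of receptors, Vipr1, a receptor of vasoactive intestinal peptide, and Steap4, a metalloreductase, were at least 12.7-fold, 12-fold and 18.1-fold lower. MHC class II genes had a median of -1.08 with 0 of 6 passing, 4 adjusted over the list alone (adjusted p = 0.00111; adjusted p = 0.31 with an estimated correlation). Epcam, the only 1 of 4 measured cholangiocyte markers that passed, was 1.73-fold lower (SE 0.12, adjusted p = 0.00801), while Sox9 did not pass (log2 difference 0.05, SE 0.28, adjusted p = 0.961).

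Of the metabolic lists, cholesterol synthesis was lower in 8c: 8 of 24 genes were lower, among them Msmo1, Sqle and Mvd by 1.45-fold to 1.59-fold (median -0.31, adjusted p = 1.25e-09; adjusted p = 0.156 with an estimated correlation; 14 lower and 1 higher adjusted over the list alone). YAP targets had a median of -0.41 with Ajuba, Ccn1 and Crim1 lower (3 of 8), and Nrf2 targets a median of -0.22 with Gstp1 and Ugdh lower (2 of 14). Fatty acid synthesis (median -0.12, 0 of 18 passing), respiratory chain subunits (0.10, 0 of 38) and the unfolded protein response (0.07, 0 of 17) also passed the set test, with adjusted p from 8.09e-07 to 0.0332 over these 5 lists and from 0.126 to 0.317 with an estimated correlation. The calls of fatty acid synthesis and the unfolded protein response were lost without some single arrays or experiments. Lost were also, without a replicate block, the calls of YAP targets (adjusted p = 0.151), fatty acid synthesis (adjusted p = 0.325) and the unfolded protein response (adjusted p = 0.128), and within slide 1 those of YAP targets (adjusted p = 0.0671), fatty acid synthesis (adjusted p = 0.108), respiratory chain subunits (adjusted p = 0.0556) and ploidy regulators (adjusted p = 0.101). Within slide 2 those of Nrf2 targets (adjusted p = 0.13) and the unfolded protein response (adjusted p = 0.54) were lost, the latter also without the arrays with acinar transcripts (adjusted p = 0.621). The other tested lists did not pass. Their medians were -0.006 for hepatocyte identity genes, -0.08 for fetal liver genes (2 of 9 lower, among them Prom1 at 2.21-fold), -0.03 for acute phase genes (Hamp higher, Steap4 lower), -0.03 for cytochrome P450 genes (2 of 36 lower), 0.005 for fatty acid oxidation (Decr1 higher), -0.08 for bile acid genes (2 of 18 lower), 0.01 for ribosome biogenesis, 0.06 for immediate early genes, -0.02 for glycolysis, -0.004 for the interferon response and -0.07 for lymphocyte markers. The mean or the test had the other sign for hepatocyte identity genes (mean -0.01, test upward) and ribosome biogenesis (mean -0.02, test upward), and the signs of several of these medians turned with another scaling. Too few members of the cholangiocyte, neutrophil and erythroid lists were measured for a test (medians -0.13, -0.31 and -0.35 over 4, 1 and 4 genes). Afp and Alb had log2 differences of 0.12 (SE 0.07) and -0.14 (SE 0.14).

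Leaving out experiments 1 to 5 in turn gave 66 and 116, 120 and 122, 77 and 155, 71 and 182, and 48 and 49 genes higher and lower. Without a replicate block 6 genes were higher and 34 lower, with the slide in place of the experiment 25 and 71, within slide 1 alone 6 and 12, within slide 2 alone 0 and 0, without experiments 1 and 2 3 and 6, and without the 6 arrays with acinar transcripts 0 and 0. Within slide 1 only experiments 1 and 2 had an 8c array beside their 2c and 4c arrays, and within slide 2 only experiments 4 and 5. The fits within a slide cannot tell an effect of the slide from that of fewer arrays. Without the 6 arrays with acinar transcripts only the 8c arrays of experiments 4 and 5 remained. That fit cannot tell an effect of acinar transcripts from that of fewer arrays. At an unadjusted p under 0.05 limma gave 1095 and 1476 with all arrays. Within slide 1 and slide 2 the list medians were 1.62 and 2.37 for mitosis, -0.92 and -0.58 for pericentral genes, 0.38 and 0.08 for periportal genes, -2.62 and -1.26 for Kupffer, -2.23 and -3.72 for stellate and -0.71 and -0.41 for endothelial markers, and the periportal call was lost within slide 2 (adjusted p = 0.0694) and the endothelial call within slide 1 (adjusted p = 0.0556). Without the arrays with acinar transcripts the periportal median was 0.055 (adjusted p = 0.0657), the endothelial -0.23 (adjusted p = 0.00473) and the Kupffer -1.81 (adjusted p = 9.16e-07).

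**Figure D2:**
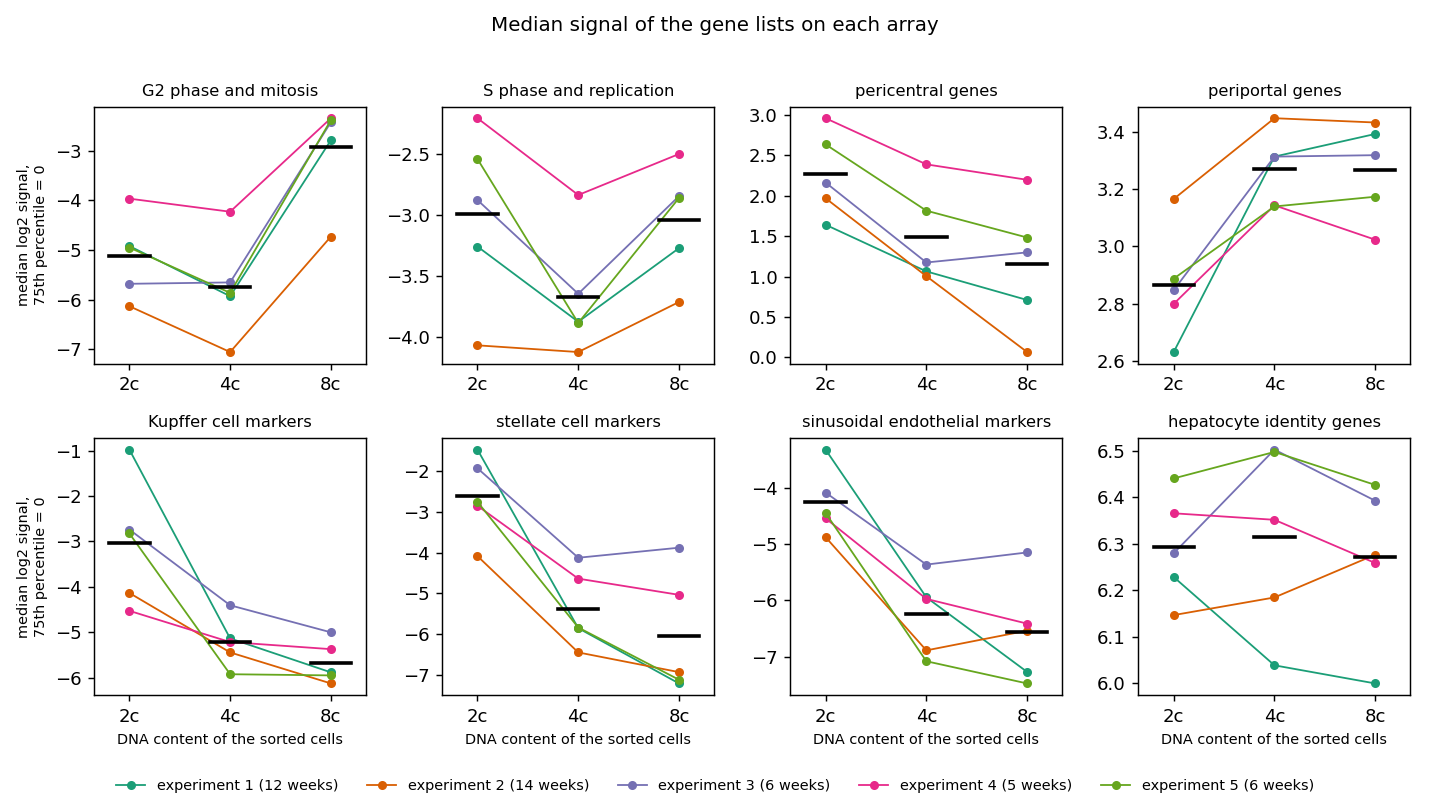
Median signal of 8 gene lists (log2, 75th percentile of the array = 0) on each array by DNA content, with arrays of the same experiment joined and the group mean (n = 5) as a black bar. Mitotic genes are higher in 8c in all 5 experiments, pericentral genes and markers of Kupffer, stellate and endothelial cells are highest in 2c, and hepatocyte identity genes are shown for comparison.

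**Figure D3:**
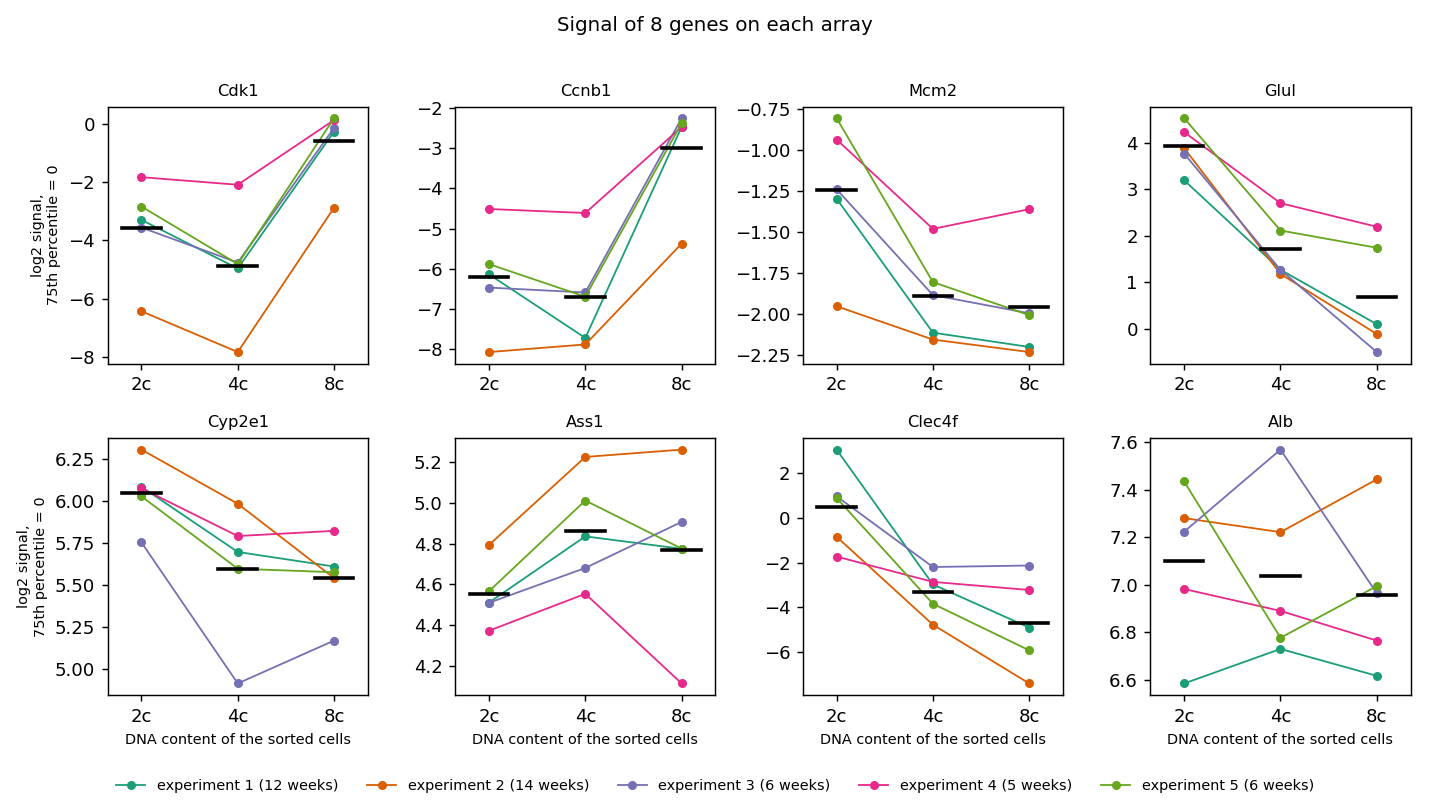
Signal of 8 genes (log2, 75th percentile of the array = 0) on each array by DNA content, with arrays of the same experiment joined and the group mean (n = 5) as a black bar. Cdk1 and Ccnb1 are higher in 8c than in 4c and 2c, Glul and Clec4f are highest in 2c, and Alb differs by -0.14 between 8c and 2c.

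The comparison of 4c with 2c cells asks what separates the first polyploid fraction from diploid cells. Of 16 Kupffer, 13 stellate and 13 endothelial markers, 8, 8 and 5 were lower in 4c than in 2c, as were 3 of 21 pericentral genes. No list passed with an estimated correlation. Of 28 genes of S phase 5 were lower in 4c, among them the helicase subunits Mcm2, Mcm3 and Mcm5 (log2 differences -0.64, -1.28 and -1.11, SE 0.12, 0.22 and 0.20, adjusted p from 0.036 to 0.0434) and the cyclin gene Ccne1 (at least 1.92-fold, SE 0.17, adjusted p = 0.0396). In all, 40 genes were higher and 163 lower in 4c, 5 and 98 of them by at least 2-fold. Scaled to the 75th percentile over all probes, 69 were higher and 106 lower.

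The S phase list had a median of -0.47 (18 of 28 lower adjusted over the list alone, adjusted p = 1.34e-10; adjusted p = 0.127 with an estimated correlation). Mitotic genes had a median of -0.38 with 0 of 33 passing (adjusted p = 0.004; adjusted p = 0.684 with an estimated correlation). Cdk1, Mki67, Top2a and Ccnb1 had log2 differences of -1.30, -0.77, -0.31 and -0.49, none passing. Of the 21 pericentral genes 3 were lower, Glul 4.65-fold (SE 0.28, adjusted p = 0.0142), Slc1a2 4.73-fold (SE 0.28, adjusted p = 0.0144) and Oat, ornithine aminotransferase, 1.76-fold (SE 0.11, adjusted p = 0.0144), and 17 were lower adjusted over the list alone (median -0.55, adjusted p = 1.13e-13; adjusted p = 0.126 with an estimated correlation). Cyp2e1 missed the threshold (log2 difference -0.45, SE 0.10, adjusted p = 0.0696). Among 21 periportal genes, Uroc1, urocanate hydratase, was 1.30-fold higher (SE 0.08, adjusted p = 0.0485), 9 were higher adjusted over the list alone, and the median was 0.29 (adjusted p = 2.84e-09; adjusted p = 0.156 with an estimated correlation).

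Lrat, which stores retinol in stellate cells, was at least 8.13-fold lower in 4c than in 2c (SE 0.56, adjusted p = 0.0144), Bgn 17.4-fold (SE 0.73, adjusted p = 0.0379) and Ctss at least 12.1-fold (SE 0.69, adjusted p = 0.0388). Clec4f, 13.8-fold lower, missed the threshold (adjusted p = 0.0573). Of the Kupffer, stellate and endothelial markers 8, 8 and 5 were lower, 12, 9 and 9 adjusted over the list alone, with 1 stellate marker higher. Their medians were -2.69, -2.85 and -2.24 (adjusted p = 4.65e-12, adjusted p = 1.03e-07 and adjusted p = 9.62e-08), and none passed with an estimated correlation (adjusted p = 0.156, adjusted p = 0.156 and adjusted p = 0.126). Without experiment 3 the endothelial median was -0.46. MHC class II genes had a median of -0.76 with 0 of 6 passing (adjusted p = 0.024; adjusted p = 0.535 with an estimated correlation). Genes higher in 4c were Bst2, an interferon-induced membrane protein, 3.56-fold higher (SE 0.25, adjusted p = 0.0161), Tmem125, at least 2.27-fold (SE 0.20, adjusted p = 0.0344), Exoc3l4, 1.79-fold (SE 0.12, adjusted p = 0.0195) and Igfbp2, an insulin-like growth factor binding protein, 1.74-fold (SE 0.14, adjusted p = 0.0354), each higher in 5 of 5 experiments. The interferon list that holds Bst2 did not pass (median -0.07, 1 of 19 higher).

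Of the remaining lists, cholesterol synthesis (-0.11), Nrf2 targets (-0.13, Gstp1 lower), the unfolded protein response (0.08), immediate early genes (0.21) and p53 targets (0.09) passed the set test, with adjusted p from 0.00524 to 0.0448 and, with an estimated correlation, from 0.126 to 0.595. The p53 median turned to -0.05 with normexp background correction and to -0.006 with the mean of a gene's probes. The calls of p53 targets, MHC class II genes, cholesterol synthesis and Nrf2 targets were lost without some single arrays or experiments. Without a replicate block the calls of mitosis (adjusted p = 0.0735), p53 targets (adjusted p = 0.146), cholesterol synthesis (adjusted p = 0.815) and Nrf2 targets (adjusted p = 0.0923) were lost, within slide 1 those of MHC class II genes (adjusted p = 0.118) and cholesterol synthesis (adjusted p = 0.204), and within slide 2 those of p53 targets (adjusted p = 0.374), immediate early genes (adjusted p = 0.232) and Nrf2 targets (adjusted p = 0.587). Without the arrays with acinar transcripts those of mitosis (adjusted p = 0.0597), p53 targets (adjusted p = 0.0865), MHC class II genes (adjusted p = 0.0552) and immediate early genes (adjusted p = 0.0521) were lost. Of the 14 other tested lists none passed, hepatocyte identity among them (median -0.04, 0 of 24), and besides Bst2 the members that passed were Ccne1 (ploidy regulators), Prom1 (fetal liver genes) and Steap4 (acute phase genes), all lower in 4c. Median, mean and test did not share a sign for 7 of these lists, lymphocyte, hepatocyte identity, acute phase, fatty acid synthesis, fatty acid oxidation, ribosome biogenesis and glycolysis. Epcam was 1.53-fold lower (SE 0.12, adjusted p = 0.0434).

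Without a replicate block 0 genes were higher and 3 lower in 4c, with the slide in place of the experiment 1 and 4, within slide 1, within slide 2, without experiments 1 and 2 and without the arrays with acinar transcripts 0 and 0. Leaving out experiments 1 to 5 in turn gave 3 and 43, 6 and 22, 0 and 16, 86 and 167, and 0 and 2 genes higher and lower, and leaving out the 2c array of experiment 4 alone 222 and 329. At an unadjusted p under 0.05 limma gave 998 and 1753. Within slide 1 and slide 2 the medians were -0.33 and -0.57 for S phase, -0.53 and -0.46 for pericentral genes, 0.30 and 0.22 for periportal genes, -2.30 and -1.23 for Kupffer, -2.30 and -2.93 for stellate and -0.56 and -0.21 for endothelial markers, whose call was lost within slide 1 (adjusted p = 0.0834). The call of the mitosis list was lost within slide 2 (median -0.39, adjusted p = 0.066).

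The comparison of 8c with 4c cells asks what changes between the polyploid fractions. Among the genes that passed it was almost wholly a rise: 106 genes were higher in 8c and 2 lower, 81 and 1 of them by at least 2-fold. With array quality weights 220 were higher and 44 lower, and at an unadjusted p under 0.05 limma gave 784 and 548. Of 33 mitotic genes 27 were higher, with a median log2 difference of 2.99. Markers of Kupffer, stellate and endothelial cells and the zonation genes, some of which differed between 2c and the others, gave 0 genes past the threshold here. Of 16 Kupffer, 13 stellate and 13 endothelial markers only 6, 5 and 5 were well above background on every 8c array. A difference between 8c and 4c in the dim markers could thus go unseen.

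Cdk1 was at least 17.1-fold higher in 8c than in 4c (log2 difference 4.30, SE 0.34, adjusted p = 0.00039). The cyclin genes Ccna2 and Ccnb1 were at least 11.6-fold and 10.6-fold higher (SE 0.42 and 0.40, adjusted p = 0.00114 and adjusted p = 0.0015), Cdca3 at least 14.6-fold (SE 0.37, adjusted p = 0.000618), Prc1, which bundles the microtubules of the central spindle, at least 10.3-fold (SE 0.42, adjusted p = 0.00132), and Mki67 at least 8.56-fold (SE 0.24, adjusted p = 0.00039). These genes were well above background on all 5 8c arrays and on 4, 1, 1, 3, 1 and 4 of the 5 4c arrays, and each was higher in 5 of 5 experiments. The mitosis list passed (adjusted p = 1.05e-69; adjusted p = 0.0777 with an estimated correlation), with 31 of 33 higher adjusted over the list alone and a median of 0.88 with normexp background correction and of 1.34 among features well above background on all arrays. Of 28 genes of S phase 6 were higher, among them Rrm2 at least 15.9-fold (SE 0.36, adjusted p = 0.000618), the chromatin assembly factor gene Chaf1b at least 2.63-fold (SE 0.22, adjusted p = 0.0165), Tk1 2.16-fold (SE 0.16, adjusted p = 0.0108) and Gins1 1.87-fold (SE 0.16, adjusted p = 0.0334). That list had a median of 0.28 (10 adjusted over the list alone, adjusted p = 2.28e-13; adjusted p = 0.126 with an estimated correlation). Of the ploidy regulators 5 of 22 were higher, among them Cdk1, Plk1, Ect2 and Foxm1 (median 0.09, adjusted p = 0.000307; adjusted p = 0.126 with an estimated correlation).

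Between 8c and 4c Glul had a log2 difference of -1.02 (SE 0.28, adjusted p = 0.277), Clec4f -1.38 (SE 0.80, adjusted p = 0.69) and Cyp2e1 -0.05 (SE 0.10, adjusted p = 0.915). The pericentral list, with 0 of 21 genes passing and 4 adjusted over the list alone, had a median of -0.22 (adjusted p = 3.4e-07; adjusted p = 0.156 with an estimated correlation), and of -0.04 without the arrays with acinar transcripts (adjusted p = 0.189). Cholesterol synthesis (-0.13), fatty acid synthesis (-0.09), respiratory chain subunits (0.08) and immediate early genes (-0.14) also passed, with 0 genes past the threshold and adjusted p from 5.04e-08 to 0.0118, or from 0.104 to 0.51 with an estimated correlation. The calls of fatty acid synthesis (adjusted p = 0.141) and immediate early genes (adjusted p = 0.0616) were lost without a replicate block, that of immediate early genes also within slide 1 (adjusted p = 0.852), and that of respiratory chain subunits within slide 2 (adjusted p = 0.572) and without the arrays with acinar transcripts (adjusted p = 0.0708). The Kupffer, stellate and endothelial medians were -0.26, -0.38 and 0.002 with 0 genes passing, and the Kupffer and stellate lists passed within slide 1 (-0.38 and -0.62, adjusted p = 0.0104 and adjusted p = 0.0402). Without the arrays with acinar transcripts the stellate list (-0.81, adjusted p = 0.00504), MHC class II genes (-0.44, adjusted p = 0.00574) and acute phase genes (-0.15, adjusted p = 0.026) passed, the last also within slide 2 (-0.12, adjusted p = 0.0489), and bile acid genes within slide 1 (-0.065, adjusted p = 0.0209). The periportal median, 0.03, did not pass, and turned to -0.05 within slide 2 (adjusted p = 0.0315) and to -0.08 without the arrays with acinar transcripts (adjusted p = 0.0264). Median, mean and test did not share a sign for 6 lists that did not pass, periportal, fetal liver, endothelial, ribosome biogenesis, glycolysis and interferon genes. The 2 genes lower in 8c were Stac (log2 difference -1.18, SE 0.15, adjusted p = 0.00553) and LOC103692122 (-0.87, SE 0.16, adjusted p = 0.0369), both chosen after their values were seen, and dim, with 1 and 3 of the 5 8c arrays well above background.

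Without a replicate block no gene passed between 8c and 4c, 0 higher and 0 lower, with the slide in place of the experiment 41 and 0, within slide 1 alone 9 and 0, within slide 2 alone 0 and 0, without experiments 1 and 2 1 and 0, and without the arrays with acinar transcripts 0 and 0. Leaving out experiments 1 to 5 in turn gave 56 and 1, 123 and 4, 55 and 0, 42 and 3, and 54 and 1, and at an unadjusted p under 0.05 limma gave 784 higher and 548 lower. Within slide 1 and slide 2 the mitosis median was 1.71 and 2.77, the S phase median 0.34 and 0.37, and the pericentral median -0.34 and -0.08.

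The 406 genes that differed between 8c and 2c show where 4c stood between them. Of the 266 genes lower in 8c, 238 (89.5%) had a 4c mean between the others, and the median ratio of the 4c minus 2c difference to the 8c minus 2c difference was 0.80. The 140 genes higher in 8c had a median ratio of 0.07, with 66 (47.1%) between. Over all 406 the share was 74.9% and the ratio 0.74, with ratios of 0.59 to 0.79 in single experiments. Simulated noise with no difference between the groups, in which the shared 2c arrays alone create such a relation, gave 78.7% and 0.49. With the 2c arrays split so that the differences shared none, the ratio was 0.51 to 0.84 over 20 splits. The genes were still chosen with all 2c arrays, and simulated noise was not run for the splits. They thus cannot show whether the relation holds apart from the shared arrays. Without experiment 5 the share was 58.8% and the ratio 0.48, and with only the 2 groups compared in each fit 50.9% and 0.11. Genes higher in 8c made up 34.5% of the 406 calls, 49.5% without experiment 5 and 56.5% with only the 2 groups compared. The pooled share and ratio thus also depend on the mix of higher and lower genes.

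**Figure D4:**
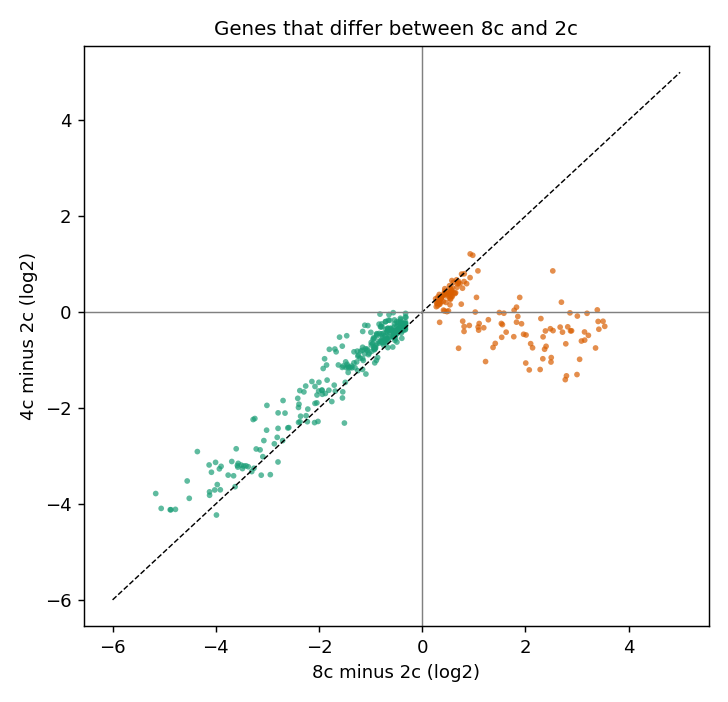
Difference between 4c and 2c against the difference between 8c and 2c (both log2) for the 406 genes that differ between 8c and 2c, each gene a point, with genes higher in 8c in orange, genes lower in green, and equality as a dashed line. The median ratio of the differences is 0.80 for the 266 lower genes and 0.07 for the 140 higher genes.

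Whether the 8c against 2c difference depended on age was tested with experiments 1 and 2 (12 and 14 weeks) against experiments 3 to 5 (5 and 6 weeks). No gene passed (0 of 17279 with limma, lowest adjusted p = 0.768), and 802 had an unadjusted p under 0.05. On simulated data the same test recovered 60.0% of 100 genes changed by log2 2 in the older experiments. Over the 27 lists the age term passed for 11 with the preset correlation and for 0 with an estimated correlation (lowest adjusted p = 0.603). That list test was added after the data were seen. Both older experiments lie on slide 1, where the younger ones have only 2c and 4c of experiment 3.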

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

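The tests of explanations and the counts of other splits given here were chosen after the results had been seen. Of 246 values tested for an array far from the others of its group, 24 met the criterion, and chance alone gives about 5%. Most of them concern mitotic genes on the 8c array of experiment 2, from the oldest animals (14 weeks), which is also 1 of the 6 arrays with acinar transcripts. That array lay below the next lowest 8c array, with a log2 gap of -2.43 for Ccna2, -2.90 for Ccnb1, -2.78 for Cdca3, -2.61 for Cdk1, -2.97 for Cenpw, -2.55 for Ect2, -2.72 for Knstrn, -2.60 for Mki67, -2.25 for Plk1, -2.47 for Prc1, -2.66 for Rrm2, -2.08 for Spag5, -2.73 for Top2a, -1.90 for Troap and -2.14 for Ube2c. The gap was -1.95 for the median of the mitosis list, of whose 33 genes 30 were lowest on that array among the 8c arrays, and -0.60 for the fatty acid oxidation list. Experiment 2 also had the lowest mitosis median in 2c (-6.135) and 4c (-7.06), besides 8c (-4.73), so the low values were not particular to 1 array. A gene was tested only in groups with all arrays well above background, which left out several mitotic genes in 2c and 4c. The 8c array of experiment 1 (12 weeks) stood at -2.785.

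Each of the other values concerned a single array. Ajuba was lowest on 2c of experiment 2, with a gap of -1.22 to the next array, and Ddhd1 on 4c of experiment 4 (-0.61). Bst2 was highest on 4c of experiment 1 (0.96), Decr1 on 2c of experiment 1 (0.30), Mcm2 on 8c of experiment 4 (0.63), and the fetal liver list on 4c of experiment 2 (0.54). The respiratory chain list was lowest on 8c of experiment 1 (-0.19).

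For 5 of 81 list differences both older experiments moved 1 way and all 3 younger experiments the other way, where chance gives 6.25%. Those of 8c against 2c are covered by the age term, which passed for 0 of the 27 lists with an estimated correlation (lowest adjusted p = 0.603), and those of the other comparisons were not tested. The mean of the older minus that of the younger experiments was -0.12 for fatty acid oxidation and -0.15 for ribosome biogenesis in 8c against 2c, -0.12 for bile acid genes in 8c against 4c, and -0.076 for glycolysis and -0.14 for the interferon response in 4c against 2c.

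Markers of Kupffer, stellate and sinusoidal endothelial cells were lower in 8c than in 2c for 38 of 42 measured genes. A scaling factor per array would move all genes alike and is argued against as the whole cause, since the median of the 42 genes minus that of the hepatocyte identity genes was -2.68 (SD between genes 1.73). The size depends on the background correction and stays open, since with normexp, which compresses dim genes, 39 genes were lower but the median was -0.82 (SD 0.85), within 1 SD of 0. That the 38 genes span the 3 cell types restates the pattern and is no test of its cause. Cells of other types in the 2c gate remain a candidate explanation, since the sort by DNA content would not remove diploid cells of any type. Diploid hepatocytes that express these genes cannot be told apart from them, since the hepatocyte identity list differed by -0.006 (SD between experiments 0.09), which a small share of other cells would give as well.

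Mitotic genes were higher in 8c than in 2c in all 5 experiments, at least 0.99 in the median of the list. Pairs of 4c cells read as 8c would carry the RNA of 4c cells, and as the whole cause they are argued against by the 108 genes that differed between 8c and 4c, against at most 3 in other splits of those arrays, and by the mitosis median of 2.99 between 8c and 4c, 1.71 within slide 1 and 2.77 within slide 2. Tetraploid hepatocytes in G2 phase or mitosis inside the 8c gate remain a candidate explanation, since the mitosis median exceeded the S phase median by 2.46 (log2). Octoploid hepatocytes that express mitotic genes themselves cannot be told apart from them, since that gap and the lowest experiment median, 0.99, fit either. No array holds sorted cells of known phase. Diploid cells in G2 phase or mitosis would likewise fall in the 4c gate, yet the mitosis median of 4c against 2c was -0.38. It was below 0 in 5 of 5 experiments, with 0 of 33 genes passing, which does not decide for the 8c gate. The age of the animals stays open and untested for the low values of experiment 2.

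Pericentral genes were lower in 8c than in 2c. Dilution of hepatocyte RNA by other cell types in 2c would lower these genes there and is argued against by their median of -0.76 (SD between experiments 0.20). That median is the pattern itself, so the argument rests on its direction alone and is no separate test. More cells from around the central vein in the 2c gate stay open as a candidate explanation: the periportal median lay on the other side, at 0.21 (SD 0.19), but 17 of 100 splits of the arrays gave a median as large (highest 0.35), and its call was lost within slide 2 (0.077) and without the arrays with acinar transcripts (0.055). Lower pericentral expression in cells of the same place cannot be told apart from it, since the median of 8c against 4c, -0.22 (SD 0.18), would follow from either and no array holds cells of known place.

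Whether chance could give as many genes was asked with 100 of the 126 splits of the 10 arrays in each comparison, the real split included. For 8c against 2c, with 406 genes, only 1 split, the real one, gave as many, and the highest other gave 2. For 4c against 2c, with 203 genes, it was again 1 split, and the highest other gave 130. That other split differs from the real one by a single exchange, of 4c of experiment 3 with 2c of experiment 4, and parted 3 of the 5 pairs. For 8c against 4c, with 108 genes, 1 split gave as many, and the highest other gave 3. So the real split gave more genes than each other drawn split, in fits in which the third group also enters. This does not exclude chance, since most drawn splits, unlike the real one, keep both arrays of some experiment on 1 side. With only the 2 groups compared the genes higher and lower were 61 and 47, 0 and 0, and 0 and 0 in the 3 comparisons. The 11 drawn splits that parted all pairs, as the real split does, gave at most 2, 0 and 0 genes in the 3 comparisons, but such splits are too few for a share under 0.05. The number of lists that passed was 14 for 8c against 2c (3 splits with as many, highest other 14), 13 for 4c against 2c (3 splits, highest other 13) and 8 for 8c against 4c (13 splits, highest other 13). Here too chance is not excluded. Among the splits that parted all pairs the highest were 10, 11 and 7 lists, again too few splits for a share under 0.05. Splits of the arrays commonly gave several lists, with a median of 6, 5 and 5, so a list that passed with the preset correlation is weaker evidence than its adjusted p. For 8c against 2c, 53 of 100 splits gave a median as large for ploidy regulators and 22 for the unfolded protein response. For 8c against 4c it was 50 for ploidy regulators, 16 for S phase and 13 for pericentral genes. For mitosis in both, and for pericentral genes in 8c against 2c, it was 1, the real split. The highest other medians came close, at 2.278 and 2.775 for mitosis and 0.745 for pericentral genes (sign ignored). For Kupffer, stellate and endothelial markers it was 4, 3 and 3 in 8c against 2c, with highest other medians of 3.563, 3.855 and 2.479. In 4c against 2c it was 5, 6 and 2 for these markers. For the dependence on age the 10 splits of the 5 experiments are too few for a share under 0.05, with 0 genes in the real split, 0 at most in the others and as many in all 10.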

How the results depend on the processing

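Experiment and slide in the same model, each slide alone, and the fits without the arrays of low weight, without the arrays with acinar transcripts and without experiments 1 and 2 were chosen as alternatives after the data had been seen, and the remaining alternatives before. In the order 8c against 2c, 4c against 2c and 8c against 4c, the genes higher and lower numbered 140 and 266, 40 and 163, and 106 and 2. They became 177 and 201, 44 and 100, and 98 and 2 with quantile normalization, 186 and 214, 49 and 123, and 111 and 2 with the median as the scaling point, 226 and 191, 69 and 106, and 104 and 2 with the 75th percentile over all probes, and 66 and 118, 6 and 47, and 64 and 1 with normexp background correction. Without the filter on dim probes they were 73 and 152, 0 and 0, and 72 and 4 over 36832 features, and among the 13544 features well above background on all arrays 76 and 147, 38 and 90, and 40 and 0. The deposited value table gave 140 and 266, 40 and 161, and 106 and 2, the mean of all probes of a gene 131 and 279, 34 and 169, and 104 and 2, array quality weights 261 and 461, 75 and 238, and 220 and 44, and eBayes with trend and robust 226 and 323, 99 and 236, and 137 and 4. No replicate block left 6 and 34, 0 and 3, and 0 and 0 genes, the slide in place of the experiment 25 and 71, 1 and 4, and 41 and 0, and experiment plus slide 80 and 158, 13 and 85, and 64 and 1. Only experiment 3 lies on both slides, so beside the experiment the slide term fits its 8c array alone. Experiment plus slide is thus close to leaving that array out (78 and 154, 13 and 82, and 64 and 1) and does not control for the slide. Fewer arrays entered the fits with only the 2 groups compared (61 and 47, 0 and 0, and 0 and 0), slide 1 alone (6 and 12, 0 and 0, and 9 and 0), slide 2 alone (0 and 0, 0 and 0, and 0 and 0), 2c of experiments 1 and 4 and 4c of experiment 3 left out for their low weight (86 and 205, 72 and 187, and 37 and 6), the 6 arrays with acinar transcripts left out (0 and 0, 0 and 0, and 0 and 0) and experiments 1 and 2 left out (3 and 6, 0 and 0, and 1 and 0). A requirement of at least 2-fold left 66 and 134, 5 and 98, and 81 and 1. The cause of a moved count was not tested, also where fewer genes or arrays entered. Without the arrays with acinar transcripts only the 8c arrays of experiments 4 and 5 remained.

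The scaling moved the balance of the calls: genes higher in 8c made up 34.5% of the calls against 2c, 46.8% with quantile normalization, 46.5% with the median and 54.2% with all probes. For 4c against 2c the shares were 19.7%, 30.6%, 28.5% and 39.4% in the same order. The median of all genes moved by at most -0.084 (log2, normexp) under a change of scaling or background correction, and by -0.125 without the filter.

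The share of genes with 4c between 2c and 8c moved from 74.9% to 84.3% with probes well above background on all arrays, 50.9% with only the 2 groups compared, 66.7% within slide 1, 88.9% without experiments 1 and 2, and the median ratio from 0.74 to 0.82 with no replicate block, 0.11 with only the 2 groups compared, 0.61 within slide 1, 0.52 without experiments 1 and 2. Slide 2 alone and the fit without the arrays with acinar transcripts called no gene between 8c and 2c, so neither gave a share or a ratio. The pooled share and ratio also depend on the mix of higher and lower genes among the calls, which differed between these fits.

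With a correlation estimated from the data no list passed. The 8c against 2c medians keep their values there, mitosis 2.37 (adjusted p = 0.0777), periportal 0.21 (adjusted p = 0.161), pericentral -0.76 (adjusted p = 0.0777), endothelial -2.32 (adjusted p = 0.126), Kupffer -3.25 (adjusted p = 0.156) and stellate -3.60 (adjusted p = 0.126). Among features well above background on all arrays, which leaves out dim markers, the endothelial median was -0.22 (adjusted p = 0.266) and the stellate -0.33 (adjusted p = 0.0723). Within slide 1 the endothelial median was -0.71 (adjusted p = 0.0556). Within slide 2 the periportal median was 0.077 (adjusted p = 0.0694), and the fetal liver list passed at -0.46 (adjusted p = 0.0489). Without the arrays with acinar transcripts the periportal median was 0.055 (adjusted p = 0.0657), the endothelial -0.23 (adjusted p = 0.00473) and the Kupffer -1.81 (adjusted p = 9.16e-07). Other medians moved by more than 1.5 times while their calls were kept: with normexp mitosis was 0.676, endothelial -0.57, Kupffer -1.05 and stellate -1.04, without the filter endothelial -1.31 and stellate -0.37, and with features well above background on all arrays mitosis 1.095 and Kupffer -1.01. Within slide 1 periportal was 0.38 and stellate -2.23, within slide 2 endothelial -0.41 and Kupffer -1.26, without experiments 1 and 2 endothelial -0.49, and without the arrays of low weight periportal 0.35 and endothelial -0.43. Of the other list differences that passed, and with the sign kept, 9 of 29 lost their call with no replicate block, 8 of 29 with the slide in place of the experiment, 7 of 29 within slide 1, 5 of 27 within slide 2 and 7 of 29 without the arrays with acinar transcripts. Lists not called with all arrays also passed within slide 1, for 8c against 2c bile acid genes at -0.165 (adjusted p = 0.00199) and immediate early genes at 0.313 (adjusted p = 0.00277), and within slide 2, for 4c against 2c fetal liver genes at -0.771 (adjusted p = 0.0134), respiratory chain subunits at 0.063 (adjusted p = 0.00134) and YAP targets at -0.308 (adjusted p = 0.014). The sign of a called median turned for ploidy regulators, 8c against 2c, with normexp (-0.078), without the filter (-0.009) and with the mean of probes (-0.009). For 4c against 2c it turned for p53 targets with normexp (-0.046) and the mean of probes (-0.006) and for Nrf2 targets within slide 2 (0.020), for 8c against 2c for the unfolded protein response within slide 2 (-0.011), and for 8c against 4c for immediate early genes within slide 1 (0.003). The periportal median of 8c against 4c, not called with all arrays, passed with the other sign within slide 2, at -0.049 (adjusted p = 0.0315), and without the arrays with acinar transcripts, at -0.084 (adjusted p = 0.0264). Changes of sign in a result that passed in neither setting are not counted as reversed. The cause of these changes was not tested, also where fewer genes or arrays entered.

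Each experiment and each array was also left out in turn. The genes higher and lower then ranged from 48 to 186 and from 49 to 341 for 8c against 2c, from 0 to 222 and from 2 to 329 for 4c against 2c, and from 42 to 138 and from 0 to 14 for 8c against 4c. The share of genes with 4c between ranged from 58.8% to 75.3%, and the ratio from 0.48 to 0.81. Without the 2c array of experiment 1 the counts moved to 4c against 2c 10 higher and 82 lower, of experiment 2 to 8c against 2c 175 lower, 4c against 2c 12 higher and 59 lower, 8c against 4c 1 lower, of experiment 3 to 8c against 2c 88 higher, 4c against 2c 1 higher and 15 lower, 8c against 4c 1 lower, of experiment 4 to 4c against 2c 222 higher and 329 lower, 8c against 4c 14 lower, of experiment 5 to 8c against 2c 82 higher and 111 lower, 4c against 2c 1 higher and 5 lower, 8c against 4c 1 lower. Without the 4c array of experiment 1 the counts moved to 4c against 2c 2 higher and 31 lower, 8c against 4c 1 lower, of experiment 2 to 4c against 2c 6 higher and 42 lower, of experiment 3 to 4c against 2c 8 higher and 41 lower, of experiment 4 to 4c against 2c 7 higher and 33 lower, 8c against 4c 66 higher, of experiment 5 to 4c against 2c 3 higher and 10 lower, 8c against 4c 4 lower. Without the 8c array of experiment 1 the counts moved to 8c against 2c 73 higher and 129 lower, 4c against 2c 20 higher, 8c against 4c 65 higher and 4 lower, of experiment 2 to 8c against 2c 177 lower, 4c against 2c 22 higher, 8c against 4c 5 lower, of experiment 3 to 8c against 2c 78 higher and 154 lower, 4c against 2c 13 higher and 82 lower, 8c against 4c 64 higher and 1 lower, of experiment 4 to 8c against 2c 92 higher, 4c against 2c 24 higher, 8c against 4c 64 higher, of experiment 5 to 8c against 2c 69 higher and 118 lower, 4c against 2c 8 higher and 44 lower, 8c against 4c 61 higher and 1 lower. No leave-out ended a call of the mitosis, pericentral, periportal, Kupffer, stellate or endothelial list between 8c and 2c, and the cause of the moved counts was not tested.

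Of 115 differences of named genes that passed, 0 turned their sign in any setting and 28 passed under every leave-out in which they were tested. Of those still measured, 115 of 115 passed with the deposited values, 102 of 115 with quantile normalization, 71 of 115 with normexp, 58 of 115 without the filter, 79 of 115 with experiment and slide, 10 of 115 with no replicate block, 10 of 82 within slide 1, 0 of 98 within slide 2, 0 of 96 without the arrays with acinar transcripts and 0 of 103 without experiments 1 and 2. In the fit with experiment and slide the slide term fits only the 8c array of experiment 3, so it does not control for the slide. In the fit without the arrays with acinar transcripts only the 8c arrays of experiments 4 and 5 remained. The age term called no gene without any single array or under any alternative in which it was run. It was not run with the slide in the model, with only the 2 groups compared, or without whole experiments, a slide or the arrays with acinar transcripts. The scan date could not be an alternative, since all arrays share 1 date and the scan runs match the slides. Signal over background limits the dim genes: a fold is given as a lower bound only where the group with the higher level was well above background on all its arrays, the log2 differences of genes dim in both groups are fitted values and no bounds, and the counts without the filter rest on more tests of noise.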

Other observations

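The tests of acinar genes were planned as follows: the list of acinar genes and its test were written after Cpa1 had been seen and before the genes of the list were, and the test on the single 4c array was chosen after its values had been seen. The levels of many genes also followed the age of the animals. Among 13537 genes well above background on all arrays, 663 had no overlap between experiments 1 and 2 (12 and 14 weeks) and experiments 3 to 5 (5 and 6 weeks), while the other splits of the experiments gave 52 to 398. Cyp3a9 was higher in the older experiments by 5.49 (log2), the retinoic acid hydroxylase gene Cyp26a1 by 3.44, Mest by 3.19 and the sulfotransferase gene Sult2a2 by 3.16. The protease inhibitor gene A2m differed by -3.21, the sterol transporter genes Abcg5 and Abcg8 by -2.99 and -2.42, Hsd11b1, which regenerates active glucocorticoid, by -2.97, Slc30a3 by -2.50 and Nrep by -2.42. Age lies between the experiments, with 2 and 3 of them in the ranges, so no test was made. Both older experiments lie on slide 1, which also holds the 2c and 4c arrays of experiment 3.

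The carboxypeptidase gene Cpa1, expressed in the pancreas, was higher in the older experiments by 6.96. RNA of pancreatic acinar cells is a candidate explanation: of 26 measured acinar genes out of 30 fixed, 25 were higher in experiments 1 and 2, with a median of 6.88. Bhlha15 was the exception at -1.81. Most of the 26 genes met the filter of 5 arrays above background only through the arrays where they were high. Their direction was thus largely set by that filter, and the count and the median are no independent support. Of the genes above background on all 15 arrays, Ctrb1, Pla2g1b and Amy2a3 differed by 7.48, 5.00 and 2.02, and Bhlha15 by -1.81. Prss1 reached 7.47 on 2c of experiment 2, Amy2a3 had a mean of 7.17 in experiment 2 and of 4.69, 3.88, 4.03 and 3.83 in experiments 1, 3, 4 and 5, and the sort by DNA content would not remove diploid acinar cells from the 2c gate. It would remove single diploid cells from the 4c and 8c gates, yet 4 of the 6 arrays with acinar transcripts are 4c or 8c, 3 of them 8c (medians 3.26, -1.48 and -1.77) and 1 of them 4c (0.98). For 4c of experiment 1 this is argued against, since the median of the acinar genes there was -8.42, below the -7.80 of the younger arrays, while Cpa1 stood at 2.89. Where the acinar transcripts come from was not tested.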
